A study of Mus musculus with 9 samples.

How the data were processed

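Messenger RNA from heart tissue of C57BL/6 mice was profiled in 3 groups of 3 libraries each: saline, angiotensin II (AngII), and AngII given with prostaglandin E1 (PGE1). Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was purified on oligo(dT) beads, fragmented and copied with random hexamers, and single-end reads of 50 bases were generated on a BGISEQ-500 sequencer. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. Doses, route and length of treatment were not given in the sources used here.

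The authors deposited 1 table of 16951 genes with an expression column for each of the 9 libraries. The deposited values are FPKM, normalized by the authors per kilobase of transcript and to the reads mapped to genes. The column header does not name this unit, and it was read from the values: the plain column sums differed by a ratio of 1.26, from 539083 to 680885, whereas the sums of value times transcript length in kilobases differed by a ratio of only 1.04. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm9 were used, with no role or order stated. The authors' deposited table also holds log2 ratios for the 3 pairs of groups, and how these were made is not given in the sources used here. The annotation used for counting, and whether strand was used, are likewise not given in the sources used here. FPKM divides by transcript length and by the reads on genes, so a few very abundant transcripts lower the values of all others, and genes with near-identical copies share reads in ways that the table does not show. No counts were used, so no count model was fitted. Steps between the lowest values of short genes with 1 transcript gave an estimate of 12.1 to 14.9 reads on genes per library in units of 1e6, which is approximate and was used in no test. The 10 most abundant genes held 16.7% to 20.2% of the summed FPKM of a library.

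Columns were assigned to groups by their names, which show the group but not which sample of the group they hold, so libraries are numbered 1 to 3 within a group in column order and the numbers pair nothing. In the workbook 11 gene symbols had been stored as dates, and all 11 were restored from the gene identifier through a RefSeq gene table, in which 99.4% of the identifiers were found. The reference annotation at hand was of another build than mm9, so no coordinates are given and it served only for gene names, transcript length and GC content.

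Values were analysed as log2(FPKM + 1), so that fold changes are on the log2(value + pseudocount) scale, with a pseudocount of 1 that understates the changes of low genes. Genes at 1 FPKM or more in at least 3 libraries were tested, 11902 in all. All 9 libraries entered 1 limma model (version 3.58.1 in R 4.3.3) with a mean per group, a trend of variance on mean expression and 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The design had been written for counts first, with this limma model named for a table that holds normalized values only. Standard errors are those of the moderated test, and means of FPKM are given with the SD over the 3 libraries of a group.

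Before the data were examined, 34 gene lists for the heart, its cell types and the treatments were fixed, and 30 of them had the 5 tested members required. The lists of lymphocyte, adipocyte, skeletal muscle and mitochondrial genome genes had fewer. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, with an estimated correlation and fry beside it. Genes are named by a rule fixed at the same time. It takes up to 10 rising and 10 falling genes of largest change, among those past the threshold that reached 5 FPKM in the higher group and did not overlap between groups, leaving out unnamed gene models, or the 5 of smallest p in a direction where fewer than 5 qualified. It adds up to 4 members of each list past its threshold, 16 genes tied to the title of the series or to hypertrophy, and 10 genes past the threshold in both AngII comparisons with opposite sign.

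Alternatives fixed in advance were the 2 compared groups only, each library left out in turn, no filter, a minimum of 5 FPKM, a pseudocount of 0.1, quantile normalization, median-ratio scaling, robust limma, an added fold threshold of 1.5, a split of the AngII libraries, an estimated correlation and fry. Alternatives for counts did not apply. A term for 2 sets of libraries seen on the first principal component, each set alone, and a correction of each library for transcript length and GC content were added after the data were seen. Those sets were defined from the expression values themselves. While the data were explored, genes were also tested between the sets, and a list of splicing factors picked after its values were seen was tested; both tests were circular, and their results were left out.

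The model was tested on simulated data for 11902 genes with the observed means and moderated residual variances, in which 100 genes were changed by 1 and 100 by 2 on the log2 scale, all drawn from genes with a mean log2 value above 2. For AngII vs saline it recovered 65% and 98% of them with 13 false calls among 176, for AngII+PGE1 vs AngII 71% and 99% with 20 among 190, and for AngII+PGE1 vs saline 61% and 98% with 10 among 169. The simulated genes varied independently, unlike the real ones, so these shares describe the calculation more than the power of the study. The simulation of unchanged groups for the shared AngII libraries used 100 draws and kept the correlation between genes. The simulated overlap of the called lists, taken by smallest p at the observed list sizes, was added after the data were seen.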

Results

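The hearts of mice treated with saline, with angiotensin II (AngII, a pressor peptide that induces cardiac hypertrophy and fibrosis) or with AngII and prostaglandin E1 (PGE1, a prostanoid that acts on the EP receptors) were compared by RNA sequencing, with 3 libraries in each group. The title of the series concerns an attenuation of hypertrophy by PGE1 through the EP3 receptor and netrin-1. Between 11049 and 11970 genes reached 1 FPKM in a library. The first principal component carried 62.3% of the variance and did not follow the groups: saline 2 and AngII+PGE1 1 lay with the 3 AngII libraries, and saline 1, saline 3, AngII+PGE1 2 and AngII+PGE1 3 lay on the other side. Libraries of the same group on different sides had a mean correlation across genes of 0.958, and libraries of different groups on the same side one of 0.978. Genes are not independent replicates, and these values describe the libraries only.

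**Figure D1:**
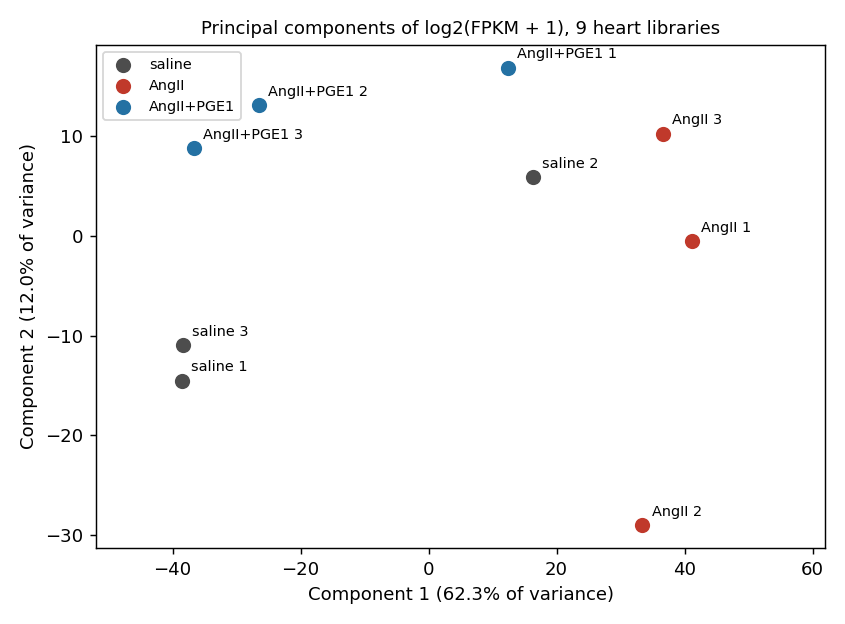
First and second principal components of log2(FPKM + 1) for the 9 libraries, 1 point per library, coloured by group. Component 1 carried 62.3% of the variance and placed saline 2 and AngII+PGE1 1 on the side of the 3 AngII libraries.

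The comparison of AngII with saline asked what the peptide changed in the heart. Some matrix, interferon-response and hypertrophy genes rose, and 16 of 31 fatty acid oxidation genes fell. Periostin (Postn), a matrix protein of activated fibroblasts, rose from 8.74 ± 2.14 to 195 ± 228 FPKM (SD, n = 3 each; log2 fold change 3.61, SE 0.79, limma adjusted p = 0.0453). Thbs4 and Timp1, an inhibitor of matrix metalloproteinases, rose by 3.39 and 2.42 on the log2 scale. AngII 2 was the highest library for all 3, with 455.92 FPKM of Postn against 37.81 and 89.91 in AngII 1 and 3. Without AngII 2 the log2 differences of Postn, Thbs4 and Timp1 were 2.63, 2.45 and 1.75 (limma adjusted p = 0.1 each). No gene at all passed in that setting, so the lost calls are not particular to these 3. The chemokine Ccl8 rose from 1.11 ± 0.169 to 13.5 ± 3.43 FPKM (SD, n = 3 each; log2 fold change 2.75, SE 0.35, limma adjusted p = 0.0178), and Ccl5 rose by 2.26. Of the 15 tested cytokine and chemokine genes 3 rose and 12 did not pass, 3 were higher and 1 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.112; adjusted p = 0.839 with an estimated correlation). Uchl1 rose by 2.26. Ccl21b, 1 of several near-identical gene copies and therefore uncertain, was listed at 0, 16.02 and 0 FPKM in the saline libraries and at 52.93, 52 and 41.67 in the AngII libraries.

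Of the 19 tested fetal and hypertrophic cardiomyocyte genes, 3 rose and 16 did not pass over all genes. Adjusted over the list alone, 8 were higher and 2 lower. The 3 that rose were Xirp2 (log2 fold change 2.04), the stress-responsive ankyrin repeat gene Ankrd1 (1.81) and Actn1 (1.17). Myh7, the fetal myosin heavy chain, was at 27.3 ± 23.6 FPKM in saline and 826 ± 804 with AngII (SD, n = 3 each), a log2 difference of 4.42 that missed the threshold (SE 1.03, limma adjusted p = 0.0503). Nppa, the atrial natriuretic peptide gene, was at 295 ± 295 and 7434 ± 5253 FPKM (SD, n = 3 each), a log2 difference of 4.67 (SE 1.16, limma adjusted p = 0.0555). Nppb (log2 difference 1.39, limma adjusted p = 0.0859) and Acta1 (1.83, limma adjusted p = 0.17) did not pass, nor did the adult myosin gene Myh6 (-0.19, limma adjusted p = 0.573). The list as a whole was called higher by camera (adjusted p = 0.0101; adjusted p = 0.839 with an estimated correlation).

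Of the 32 tested extracellular matrix and fibrosis genes, the 3 named above rose and 29 did not pass; 10 were higher adjusted over the list alone (camera adjusted p = 0.000218; adjusted p = 0.839 with an estimated correlation). Col1a1 was at 47.6 ± 10.6 FPKM in saline and 186 ± 168 with AngII (SD, n = 3 each) and did not pass (limma adjusted p = 0.0992), nor did Col3a1 (limma adjusted p = 0.28) or Ctgf (limma adjusted p = 0.337). The spread came mainly from AngII 2, with 375.52 FPKM of Col1a1 against 56.41 in AngII 1 and 124.72 in AngII 3. All 20 interferon-response genes had a positive difference and 6 rose, among them Ifit1 (log2 fold change 2.23), Ifit3 (1.63), the transcription factor Irf7 (1.51) and Ifi27l2a (1.48); 12 passed adjusted over the list alone (camera adjusted p = 6.62e-08; adjusted p = 0.839 with an estimated correlation).

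Of the 31 fatty acid oxidation genes, 16 fell and none rose; 21 were lower adjusted over the list alone (camera adjusted p = 1.85e-10; adjusted p = 0.782 with an estimated correlation; fry adjusted p = 0.00863). Etfa and Etfdh, which pass electrons from fatty acid oxidation to the respiratory chain, fell by 1.65 and 1.57 on the log2 scale, and the thioesterase Acot1 fell by 1.97. Pdk4, an inhibitor of pyruvate dehydrogenase, fell from 141 ± 62.8 to 28.4 ± 1.49 FPKM (SD, n = 3 each; log2 fold change -2.14, SE 0.47, limma adjusted p = 0.0453). The median level of the list, relative to the saline mean, was -0.08 in saline 2 and between -0.96 and -0.75 in the AngII libraries. The named members lay lower in saline 2, with Pdk4 at 68.23 FPKM against 174.38 and 179.57 in saline 1 and 3. With a term for the 2 sides of the first component, chosen after seeing the data, Pdk4, Acot1, Etfa and Etfdh differed by -1.16, -1.64, -1.30 and -1.12. Only Pdk4 of these 4 passed with the term (limma adjusted p = 0.0499). Outside the list, the acyl-CoA dehydrogenase genes Acad11 and Acad12 fell by 1.77 and 1.71. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 2.04, from 3500.39, 1102.1 and 3723.33 FPKM in saline to between 546.88 and 648.84 with AngII. Retnla, Mylk4, Dnajb9 and Htra1 fell by 2.35, 1.88, 1.77 and 1.72. The phospholipase gene Pla2g5 fell from 29.8 ± 9.25 to 6.54 ± 1.501 FPKM (SD, n = 3 each; limma adjusted p = 0.0178). Saline 2 was the lowest saline library for Acad11, Acad12, Mylk4, Dnajb9 and Htra1. With the same term for the sides their differences were -1.11, -0.88, -1.32, -1.04 and -1.14, and none passed. Retnla, at -2.84, did not pass with the term either, whereas Pla2g5, at -1.85, did (limma adjusted p = 0.0418). Agtr1a, the AngII receptor gene, fell from 19.97 ± 2.88 to 11.5 ± 1.36 FPKM (SD, n = 3 each; log2 fold change -0.74, SE 0.16, limma adjusted p = 0.0453).

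Other lists were called by camera with few members past the threshold. Of 20 potassium, sodium and pacemaker channel genes, 19 had a negative difference and Scn4b fell by 1.55, while 4 were lower adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.839 with an estimated correlation). Of 16 cAMP and CREB target genes, Rgs2, Dusp1 and Pde4d fell by 1.61, 1.44 and 0.62, and 4 were lower adjusted over the list alone (camera adjusted p = 0.00567; adjusted p = 0.839 with an estimated correlation). None of the 55 ribosomal protein genes passed over all genes or over the list alone, and 50 had a positive difference. Rps28 was at 273 ± 91.6 and 474 ± 10.95 FPKM (SD, n = 3 each), and the log2 differences of Rpl12, Rpl35 and Rps6 were 0.85, 0.91 and 0.51 (camera adjusted p = 5.64e-07; adjusted p = 0.839 with an estimated correlation). None of the 15 cell cycle genes passed over all genes or over the list alone, among them Ccna2 (1.06), Plk1 (0.66), Ccnb2 (0.85) and Aurkb (0.67), with a list median of -0.28 in AngII 3 against 0.65 and 1.24 in the other AngII libraries (camera adjusted p = 0.0202; adjusted p = 0.839 with an estimated correlation). Saline 2 lay near the AngII libraries in several of these lists: its median was 0.49 for ribosomal protein genes, against 0.41 to 0.68 with AngII, -0.36 for the channels, against -0.53 to -0.40, and -0.39 for the cAMP targets, against -0.85 to -0.38.

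In all, 370 of 11902 genes passed for AngII vs saline, 156 higher and 214 lower, and 4169 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 33.7% of all tested genes, where chance gives 10%. The balance of directions was not stable: 162 were higher and 103 lower with only these 2 groups in the model, with 186 genes shared, and 177 higher and 171 lower with median-ratio scaling. The count rested on single libraries: it was 0 without saline 1, saline 3, AngII 2 or AngII 3, 65 without AngII 1, 15 without AngII+PGE1 2, 31 without AngII+PGE1 3, 1582 without AngII+PGE1 1 and 4512 without saline 2. With a term for the 2 sides of the first component, chosen after seeing the data, 21 genes passed, 10 higher and 11 lower. Among the 5 libraries of the AngII side alone, the differences of the 370 genes were 0.706 of the full ones at the median. There 347 genes kept at least 1/2 of the full difference, and the signs could not reverse because the groups did not overlap. That side holds 1 saline library, so this is no test of stability.

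**Figure D2:**
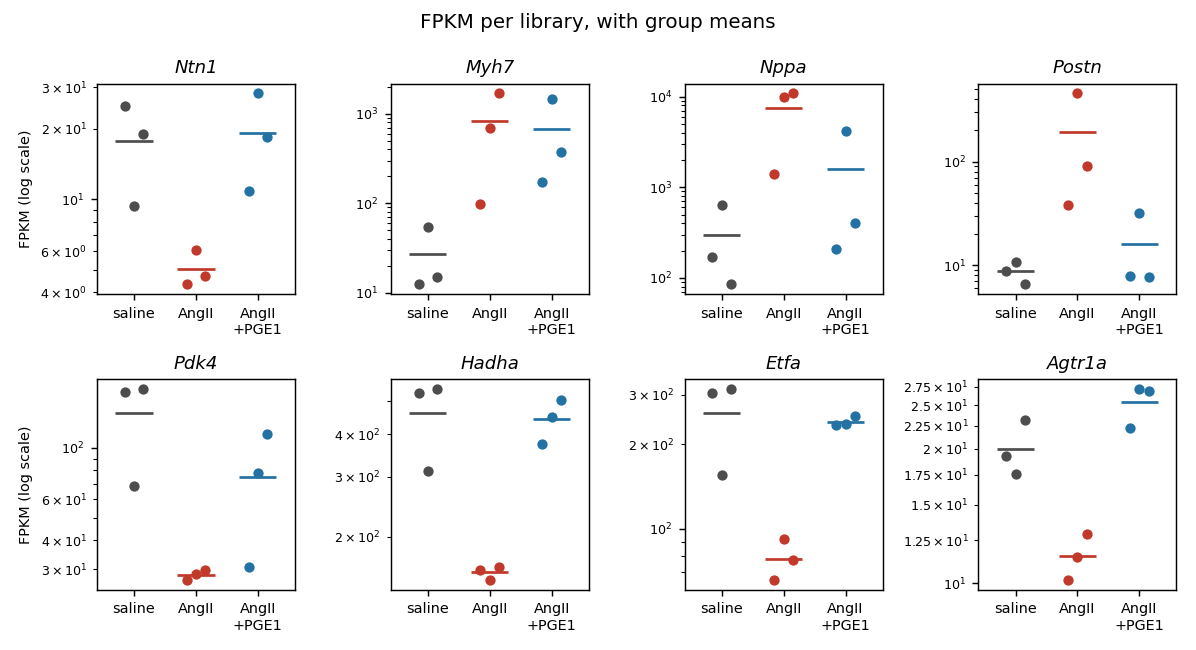
FPKM of 8 genes in each library (points) with the group mean (line), on log axes that do not start at 0. The AngII libraries lay below all others for Ntn1, Pdk4, Hadha, Etfa and Agtr1a, whereas Myh7 and Nppa of the AngII+PGE1 group spread over much of the range of the other groups.

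The comparison of AngII+PGE1 with AngII asked what PGE1 changed on top of AngII. Some fatty acid oxidation genes rose, and several genes that AngII had raised fell. Of the 31 fatty acid oxidation genes, 5 rose and none fell over all genes; adjusted over the list alone 17 were higher and 1 lower (camera adjusted p = 5.11e-09; adjusted p = 0.948 with an estimated correlation; fry adjusted p = 0.0401). Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein, rose by 1.48 and 1.29 on the log2 scale, Acadm by 1.198, and Etfa from 78.4 ± 13.2 to 241 ± 9.28 FPKM (SD, n = 3 each; log2 fold change 1.62, SE 0.26, limma adjusted p = 0.0435). Penk, the proenkephalin gene, rose from 1.23 ± 0.193 to 6.64 ± 1.04 FPKM (SD, n = 3 each; log2 fold change 1.77, SE 0.23, limma adjusted p = 0.031). Oaz1, the water channel gene Aqp1, Herpud1, Cbx7, Nubpl and H2-Q6 rose by 1.55, 1.41, 1.33, 1.30, 1.29 and 1.23. H2-Q6 belongs to a family of closely similar genes and is uncertain. Agtr1a rose to 25.4 ± 2.77 FPKM (SD, n = 3; log2 fold change 1.08, SE 0.16, limma adjusted p = 0.0395).

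Myl1, a myosin light chain gene of fetal and skeletal muscle, fell from 158 ± 21.2 to 42.0 ± 11.4 FPKM (SD, n = 3 each; log2 fold change -1.91, SE 0.23, limma adjusted p = 0.031). Tmsb10, the growth factor Igf1, Sox4, Cabp1, the leukocyte antigen Cd52 and Dynll1 fell by 1.80, 1.73, 1.55, 1.39, 1.36 and 1.35. Ccl21b was listed at 0 FPKM in all 3 AngII+PGE1 libraries. Of 20 interferon-response genes, 2 fell, Ifi27l2a by 1.55 and Ifi44 by 1.49, and 9 were lower adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.959 with an estimated correlation); the list median in AngII+PGE1 1, 0.96, lay within the AngII libraries.

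None of the 32 extracellular matrix and fibrosis genes passed over all genes, and 30 had a negative difference; 21 were lower adjusted over the list alone (camera adjusted p = 1.92e-07; adjusted p = 0.959 with an estimated correlation). Postn (-3.10, limma adjusted p = 0.0609), Col3a1 (-2.43, limma adjusted p = 0.059), Col1a1 (-2.42, limma adjusted p = 0.059), Mfap4 (-2.37, limma adjusted p = 0.0566), Sparc (-1.70, limma adjusted p = 0.0525) and Col16a1 (-1.44, limma adjusted p = 0.059) missed the threshold. None of the 15 cell cycle genes passed and 10 were lower adjusted over the list alone, among them Ccna2 (-1.47), Birc5 (-1.25), Plk1 (-1.21) and Tpx2 (-1.09), all at 0.85 FPKM or less on average with PGE1 (camera adjusted p = 0.00171; adjusted p = 0.959 with an estimated correlation). The cell cycle list median of AngII 3, -0.28, lay within the AngII+PGE1 libraries, at -0.50 to -0.11. None of the 20 channel genes passed and 3 were higher adjusted over the list alone, among Kcnj11 (0.77), Kcnh2 (0.64), Scn4b (0.91) and Gja5 (0.49) (camera adjusted p = 0.00171; adjusted p = 0.948 with an estimated correlation). The 19 fetal and hypertrophic genes held none that passed. Myh7 was at 174.21, 1451.1 and 372.21 FPKM in the AngII+PGE1 libraries (log2 difference from AngII -0.10, SE 1.03, limma adjusted p = 0.953) and Nppa at 209.4, 4176.61 and 399.06 (-2.92, SE 1.16, limma adjusted p = 0.119). Acta1 (-1.33, limma adjusted p = 0.302), Nppb (-0.90, limma adjusted p = 0.193), Ctgf (0.07, limma adjusted p = 0.94) and Myh6 (0.07, limma adjusted p = 0.854) did not pass either.

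In all, 48 of 11902 genes passed for AngII+PGE1 vs AngII, 24 higher and 24 lower, and 4005 had an unadjusted p under 0.05. The count was 0 without saline 1, AngII 2, AngII+PGE1 2 or AngII+PGE1 3, 15 without saline 3, 33 without AngII 1 (7 higher and 26 lower, 11 shared), 75 without AngII 3 (8 higher and 67 lower, 21 shared), 2434 without saline 2 and 3193 without AngII+PGE1 1. It was 772 with only these 2 groups in the model, 244 with median-ratio scaling and 6 without a filter. With a term for the 2 sides of the first component 5 genes passed, 3 higher and 2 lower. Among the 5 libraries of the AngII side alone, the differences of the 48 genes were 0.884 of the full ones at the median. All 48 kept at least 1/2 of the full difference, but that side holds only 1 AngII+PGE1 library. Camera called 5 lists here, and 8 without AngII+PGE1 1.

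The genes changed by AngII were then followed in the AngII+PGE1 libraries. Of the 370 genes, 368 had the opposite sign in AngII+PGE1 vs AngII, or 99.5%. In that comparison 37 also passed, all with the opposite sign: 17 rose with AngII and fell with PGE1, and 20 fell and rose. Independent lists would share 0.315 and 0.432, but the lists share the AngII libraries and are not independent. Lists of the same sizes from simulated unchanged groups shared 17.2 genes of opposite sign on average, over a range of 0 to 48, and 17 of 100 simulations shared 37 or more. The 10 of largest AngII change were Ccl21b, Myl1, Slc15a2, Il11 and Cd52, which were higher with AngII, and Etfa, Nubpl, Aqp1, Penk and Hadha, which were lower. Slc15a2, a peptide transporter gene, was at 0.623 ± 0.337, 4.05 ± 0.638 and 0.767 ± 0.393 FPKM in saline, AngII and AngII+PGE1 (SD, n = 3 each), and the cytokine gene Il11 at 0.69 ± 0.632, 3.96 ± 1.28 and 0.503 ± 0.429. Hadha was at 462 ± 129, 157 ± 7.51 and 443 ± 66.0 FPKM. The median fraction of the AngII change that was absent with PGE1 was 0.852 ± 0.0979 (SD over the 3 AngII+PGE1 libraries, with 0.738, 0.863 and 0.931), and 69 of the 370 lay past the saline mean. The fraction was 0.677 without saline 2 and 1.09 without AngII+PGE1 1.

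Both comparisons use the AngII libraries with opposite sign, so opposite changes arise without any effect. Simulated unchanged groups had the opposite sign for 84.1% of as many genes on average, over a range of 0% to 100%, and the correlation of fold changes across genes was -0.895 against a simulated mean of -0.498 and a simulated range of -0.983 to 0.918. The share, the correlation and the 37 shared genes thus lay within what unchanged groups gave. The covariance was -0.26 against a simulated -0.0383, over a range of -0.152 to 0.0242, a difference of -0.222. When genes were chosen with AngII 2 and AngII 3 and the change was measured against AngII 1, 86.7% of 60 genes had the opposite sign and the median fraction was 0.638; the other 2 splits chose 0 genes. The observed covariance of -0.26 lay outside the range of the simulations. The simulated groups shared the AngII libraries in the same way, so sharing alone did not give this excess there. However, the simulations drew the deviations of each library at random and did not hold the sides of the first component. All AngII libraries lay on 1 side, with only saline 2 and AngII+PGE1 1 of the other groups. The excess therefore cannot tell a return with PGE1 from the uneven share of the sides.

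**Figure D3:**
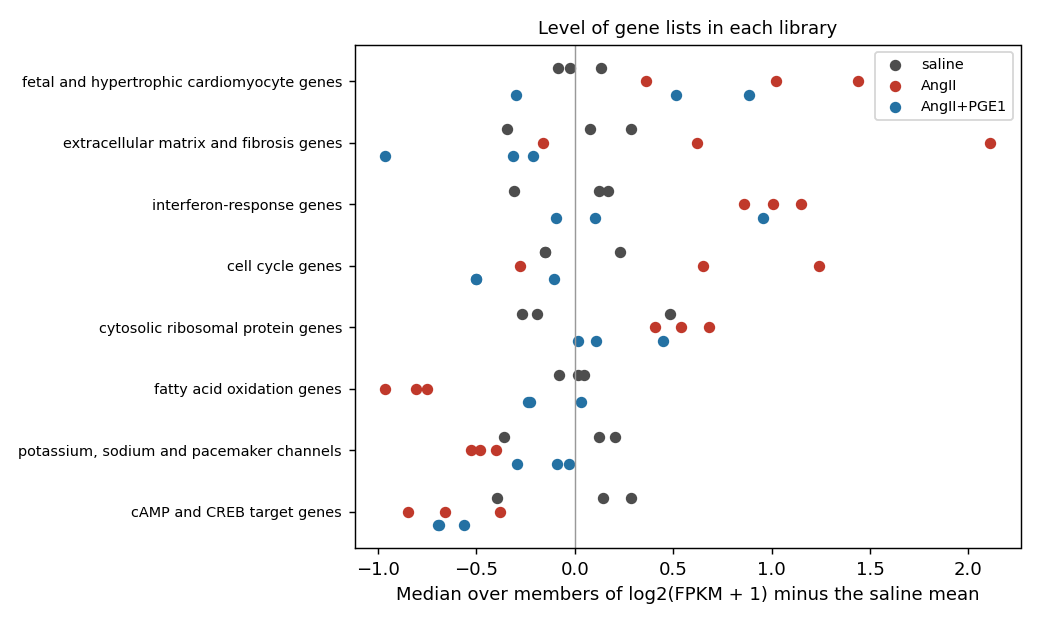
Median over the tested members of 8 gene lists of log2(FPKM + 1) minus the saline mean, 1 point per library, coloured by group. Fatty acid oxidation genes lay between -0.96 and -0.75 in the AngII libraries and between -0.24 and 0.03 in the AngII+PGE1 libraries, whereas the matrix list spread from -0.16 to 2.11 within the AngII group.

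The title of the series names netrin-1 and the EP3 receptor. Ntn1, which encodes the guidance protein netrin-1, was at 17.8 ± 7.84 FPKM in saline, 5.03 ± 0.913 with AngII and 19.2 ± 8.77 with AngII+PGE1 (SD, n = 3 each), and the AngII libraries did not overlap with either other group. Neither difference passed over all genes: AngII vs saline was -1.55 on the log2 scale (SE 0.37, limma adjusted p = 0.0522, and 0.0112 adjusted over the list alone) and AngII+PGE1 vs AngII was 1.66 (SE 0.37, limma adjusted p = 0.0566, and 0.00709 adjusted over the list alone). AngII+PGE1 vs saline was 0.11 (SE 0.37, limma adjusted p = 1). A lack of overlap was not particular to Ntn1. Of all tested genes, the AngII libraries did not overlap with saline for 33.7% and with AngII+PGE1 for 36.1%. The authors' deposited table gives log2 ratios for Ntn1 of -1.87, 2.09 and 0.23 for the 3 comparisons. The level also followed the sides of the first component: saline 2 and AngII+PGE1 1, at 9.39 and 10.85 FPKM, were the lowest of their groups, and with a term for the 2 sides the differences were -0.84 and 0.94 (limma adjusted p = 0.12 for both). Both Ntn1 differences passed without saline 2 (limma adjusted p = 0.00521 and 0.0174) and without AngII+PGE1 1 (0.0274 and 0.0164). With any other library left out neither passed. The limma adjusted p was then 0.0644 to 0.237 for AngII vs saline and 0.0795 to 0.203 for AngII+PGE1 vs AngII. Among the 6 tested netrin and netrin receptor genes, none passed for AngII vs saline over all genes and 3 were lower adjusted over the list alone, Ntn1, Neo1 (-1.196) and Ntn4 (-1.54), but not Unc5b (-0.58) (camera adjusted p = 0.04; adjusted p = 0.839 with an estimated correlation). Saline 2 lay near the AngII libraries for Neo1, at 5.32 FPKM against 4.11 to 4.68, and for Ntn4, at 0.65 against 0.36 to 0.56. With the term for the sides their differences were -0.50 and -0.34 (limma adjusted p = 0.262 and 0.394).

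Ptger3, the EP3 receptor gene, was listed at 0.07, 0 and 0 FPKM in saline, at 0.06, 0.11 and 0.08 with AngII and at 0, 0.04 and 0.05 with AngII+PGE1. These values lay below the minimum for testing, so no difference was detectable at this depth. The authors' deposited log2 ratios for Ptger3 were 2.35 for AngII over saline, -1.39 for AngII+PGE1 over AngII and 0.97 for AngII+PGE1 over saline. Ptger1, at 0.32 to 1.13 FPKM, and Ptger2, at 0.02 to 0.12, also lay below that minimum. Ptger4 was at 2.11 ± 0.471, 2.09 ± 0.412 and 1.80 ± 0.514 FPKM in the 3 groups (SD, n = 3 each) and passed in no comparison. The list of prostanoid receptors and synthesis genes passed in no comparison.

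The comparison of AngII+PGE1 with saline asked what differed from saline under both treatments. Of 11902 genes, 2 passed, both lower, and 504 had an unadjusted p under 0.05. Cldn5, a tight junction gene of endothelial cells, fell from 25.1 ± 1.199 to 8.65 ± 1.38 FPKM (SD, n = 3 each; log2 fold change -1.45, SE 0.17, limma adjusted p = 0.046), and Trp53i11 fell from 29.8 ± 4.25 to 9.21 ± 1.01 FPKM (SD, n = 3 each; -1.59, SE 0.18, limma adjusted p = 0.046). The next genes did not pass: Angptl4 (-1.90, limma adjusted p = 0.0583), Col5a3 (-1.71, limma adjusted p = 0.132) and the apelin receptor gene Aplnr (-1.56, limma adjusted p = 0.228) were lower, and Ier3 (1.27, limma adjusted p = 0.1), Ccl8 (2.19, limma adjusted p = 0.16), Ifi27 (1.35), Mid1ip1 (0.72) and Rhobtb1 (0.86) were higher. With AngII alone Cldn5 was at 18.96 ± 3.44 and Trp53i11 at 24.1 ± 4.56 FPKM (SD, n = 3 each), nearer to saline than to AngII+PGE1. Most of each fall was thus seen only where PGE1 was added. Myh7 had a log2 difference of 4.32 (SE 1.03, limma adjusted p = 0.809).

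Camera called 14 lists in this comparison, 9 higher and 5 lower, and none with an estimated correlation. List medians of the saline and AngII+PGE1 libraries overlapped for all of these except the clock, cAMP, endothelial and fibroblast lists. Of 19 fetal and hypertrophic genes 17 had a positive difference, and Myh7 and Myot (0.81) passed over the list alone (camera adjusted p = 3.27e-08; adjusted p = 0.398 with an estimated correlation). The list median was 0.89 and 0.51 in AngII+PGE1 2 and 3 but -0.30 in AngII+PGE1 1, below all saline libraries at -0.08 to 0.13. Of 55 ribosomal protein genes 54 were positive and none passed, with a list median of 0.22 (camera adjusted p = 7.51e-14; adjusted p = 0.423 with an estimated correlation). Saline 2, at 0.49, lay above all AngII+PGE1 libraries, at 0.02 to 0.45, and the difference came from saline 1 and 3, at -0.27 and -0.19. Of 20 interferon-response genes 12 were positive and 8 negative. Over the list alone 3 passed, all higher, among them Igtp (2.39) and Irf7 (1.01) but not Irgm1 (1.08) (camera adjusted p = 5.72e-07, and adjusted p = 0.423 with an estimated correlation). That list median was 0.96 in AngII+PGE1 1 but -0.09 and 0.10 in AngII+PGE1 2 and 3, within the saline libraries at -0.31 to 0.17. The other higher lists were neutrophil markers (camera adjusted p = 5.13e-06; adjusted p = 0.226 with an estimated correlation; no member past the list alone, and saline 2, at 0.52, within AngII+PGE1 at 0.41 to 0.99), clock genes (0.000151; 0.226 with an estimated correlation; 13 positive and 4 negative, with Arntl at -1.90 and Npas2 at -0.92), glycolysis (0.0022; 0.337 with an estimated correlation), oxidative stress genes (0.00793; 0.398 with an estimated correlation) and cytokines and chemokines (0.0134; 0.502 with an estimated correlation). The last 2 were nearly balanced: 11 oxidative stress genes were positive and 10 negative, with a list median of 0.04, and 8 cytokine and chemokine genes positive and 7 negative, with a median of 0.04, Ccl8 at 2.19 and Ccl9 at -0.34. The clock list median was -0.17, 0.20 and -0.13 in saline 1, 2 and 3 and 0.29 to 0.41 with AngII+PGE1, so saline 2 lay nearer to the treated libraries than the other saline libraries did. The ninth was the erythroid list, in which Hba-a1 was at 679.13, 3580.59 and 59.75 FPKM with AngII+PGE1 and at 89.44, 602.85 and 47.25 in saline (camera adjusted p = 0.00047; adjusted p = 0.423 with an estimated correlation). Of 14 endothelial markers 12 were negative, and Cldn5 alone passed (camera adjusted p = 2.68e-05; adjusted p = 0.398 with an estimated correlation). Of 16 cAMP and CREB targets 5 were lower over the list alone, among them Nr4a3, Gem, Rgs2 and Nr4a1 (camera adjusted p = 3.85e-06; adjusted p = 0.337 with an estimated correlation). Saline 2 lay near the treated libraries here too, with a list median of -0.39 against -0.70 to -0.56 and Nr4a1 at 7 FPKM against 5.45 to 8.56, where saline 1 and 3 had 65.08 and 50.78. No member passed among fibroblast markers such as Tcf21 (0.00992; 0.423 with an estimated correlation), matrix genes such as Col4a1 (-1.39), Eln (-1.23), Col4a2 (-1.17) and Sparc (-0.96) (0.00809; 0.928 with an estimated correlation) or cell cycle genes such as Plk1 (0.0346; 0.928 with an estimated correlation).

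The count of 2 genes became 0 without saline 1, saline 3, AngII 1, AngII 2, AngII+PGE1 1 or AngII+PGE1 3, 1 other gene without AngII+PGE1 2, 6 without AngII 3 and 23 without saline 2. Among the 4 libraries on the other side of the first component, 2 of each group, 321 genes passed, both of these among them. These 4 libraries were grouped by the same expression values, which can make the spread within each group small. The count of 321 and the 2 kept genes are therefore no test of stability.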

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

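Among the genes too low to be tested, 2 were listed at 0 FPKM in every saline library and above 0 in all 3 libraries of another group, with a group mean of at least 0.5 FPKM. Crabp2 had a mean of 0.93 FPKM with AngII, from 0.38, 1.29 and 1.12, and was at 0.17, 0 and 0.07 with AngII+PGE1. Hist1h4n had a mean of 0.947 FPKM with AngII+PGE1, from 0.66, 1.87 and 0.31, and was at 0.54, 0 and 0 with AngII; it is a histone gene with near-identical copies, so its reads are uncertain. An entry of 0 in a table without counts can be a failed estimate, and no difference was tested.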

How the results depend on the processing

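The term for the 2 sides of the first component, the fits to 1 side and the length and GC correction were chosen after seeing the data, and no result was replaced by them. No paired analysis was possible because the expression columns do not carry the replicate numbers of the sample titles. Alternatives for counts were not run, since the table holds none, and robust limma was not run for gene lists, since camera has no such term. The cause of the changes below was not tested, except that leaving out libraries and the fits to 1 side use fewer samples. Depth limits Ptger1, Ptger2 and Ptger3, which lay below the filter; without a filter, Ptger3 differed by 0.08 for AngII vs saline (limma adjusted p = 0.205) and -0.07 for AngII+PGE1 vs AngII (limma adjusted p = 0.258), and Ptger1 by -0.44 for AngII+PGE1 vs AngII (limma adjusted p = 0.112) and -0.34 for AngII+PGE1 vs saline (limma adjusted p = 1).

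For AngII vs saline the 370 genes became 88 without a filter, 593 with quantile normalization (361 shared), 725 with the length and GC correction (348 shared), 21 with the term for the sides (19 shared), 0 in the 5-library side alone, and 0 to 4512 with 1 library left out. The 48 for AngII+PGE1 vs AngII became 772 with only the 2 groups in the model, 6 without a filter, 244 with median-ratio scaling, 718 with the correction, 5 with the term for the sides, 2 in the 5-library side alone, and 0 to 3193 with 1 library left out. The 2 for AngII+PGE1 vs saline became 1 with only the 2 groups, 0 without a filter, 6 with the term for the sides, 321 in the 4-library side, 4 with the correction, and 0 to 23 with 1 library left out. The 4-library side was defined from these same values, so its 321 is no test of stability. The 5-library side gave 1 gene and 8 lists for this comparison, but it holds only 1 library of each of these 2 groups and takes its spread from the AngII libraries alone, so neither value is a test of the difference. That side also holds only 1 saline library for AngII vs saline, where the smallest limma adjusted p was 0.158, and only 1 AngII+PGE1 library for AngII+PGE1 vs AngII, so these counts say little about stability.

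The share of AngII genes with the opposite sign, 99.5%, was 97.7% without a filter, 100% with the term for the sides, 86.7% in the split that kept AngII 1, and 98.3% to 100% with 1 library left out. The median fraction, 0.852, was 0.638 in that split and 0.677 to 1.09 with 1 library left out. Neither had a value where no gene passed for AngII vs saline.

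The 9 lists called for AngII vs saline became 0 with an estimated correlation and 1 with fry, and 6 to 13 with 1 library left out. The 5 for AngII+PGE1 vs AngII became 0 and 1, 8 with the term for the sides (3 shared), and 4 to 8 with 1 library left out. The 14 for AngII+PGE1 vs saline became 0 with an estimated correlation and 0 with fry, and 11 to 14 with 1 library left out.

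Ntn1 kept its sign in AngII vs saline and AngII+PGE1 vs AngII under every alternative run. Its AngII libraries overlapped with neither other group, so leaving out a library or keeping 1 side could not reverse these signs. The kept sign does not show stability there. For AngII vs saline Ntn1 passed at -1.55 with only the 2 groups and with a minimum of 5 FPKM. It also passed at -1.57 with quantile normalization and at -1.51 with the correction. With 1 library left out Ntn1 ran from -1.93 to -1.27. It passed for AngII+PGE1 vs AngII at 1.66 with only the 2 groups, at 1.74 with median-ratio scaling and at 1.74 with the correction, and ran from 1.34 to 1.99 with 1 library left out. With 1 library left out, Ntn1 passed in these comparisons only without saline 2 or without AngII+PGE1 1. The value for AngII+PGE1 vs saline ran from -0.27 to 0.44. For the other named genes, of 3579 values over 188 gene and comparison pairs, 2804 kept their direction and side of the threshold, 601 lost significance, 109 gained it, 65 uncalled values changed sign, and 0 called values reversed. The called genes did not overlap between the groups, so leaving out a library or keeping 1 side could not reverse them, and the 0 does not show stability there. Of the 66 called values among them, all 66 lost significance without saline 1 or without AngII 2, and all 66 kept it without saline 2.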

Other observations

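The tests of the first component, the clock genes and Ntn1 were chosen after those results were seen; the other splits of the samples were planned. For AngII vs saline, 3 of 13 fibroblast markers fell and 2 of 19 macrophage and monocyte markers rose, though neither list was called by camera (adjusted p = 0.439 and 0.221). In the nuclear respiratory chain 9 of 55 genes fell with AngII while the list median was 0.20, the mean 0.03 and the camera direction down (adjusted p = 0.841). The clock list had a median of -0.22, a mean of 0.22 and the camera direction down in the same comparison (adjusted p = 0.907). Haemoglobin transcripts varied between libraries more than between groups: Hba-a1 ran from 47.25 to 3580.59 FPKM.

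Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. For AngII vs saline the real split called 370 genes and the highest other 1; 1 split, the real one, called as many. The real split for AngII+PGE1 vs AngII called 48 and the highest other 0, again 1 split. That for AngII+PGE1 vs saline called 2 and the highest other 2, with 2 splits calling as many. Gene lists behaved otherwise. For AngII vs saline 8 of the 10 splits called at least the real 9 lists, up to 17, and for AngII+PGE1 vs AngII all 10 called at least the real 5, up to 15. With AngII+PGE1 vs saline 1 split called 14, the real one, and the highest other 13. In the 2 comparisons with AngII, regrouped libraries thus gave as many or more list calls at the preset correlation.

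The first component set saline 2, AngII+PGE1 1 and the AngII libraries apart from the other 4 libraries. Whether a bias of transcript length and GC content was the only cause is not settled. After correction the component separated the same libraries, but the correction used 1 transcript per gene from another build and may have been incomplete. The component then carried 61.6% of the remaining variance, against 62.3% before, a share that does not show how much the correction removed. A part of such a bias is therefore not excluded. Saline 2 and AngII+PGE1 1 being AngII libraries with a wrong label is argued against by the fetal and hypertrophic list, at -0.0842 and -0.296 against 0.36 or more with AngII. Another time of day was not settled by the clock score. This score, the mean of 4 genes that peak with Arntl minus that of 9 that peak opposite, was -0.28 on average in AngII+PGE1 2 and 3. It was 2.14 in saline 1 and 3. However, AngII+PGE1 2 and 3 had also received AngII, whose effect on these genes stays open, so the score cannot decide. What else separates the libraries, such as RNA quality, handling or an untested biological difference, also stays open. Some measures of the libraries followed the 2 sides without overlap. The FPKM sums were 612409 to 680885 in the 5 libraries and 539083 to 586122 in the other 4. Genes at 0 FPKM numbered 839 to 1029 and 1177 to 1411, whereas the estimated reads on genes overlapped. Clk1, picked after its values were seen, was at 63.37 to 86.58 FPKM in the 5 libraries and 13.86 to 19.43 in the other 4.

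For most of the 13 scored clock genes, saline 1 and saline 3 stood apart from the other 7 libraries. Arntl was at 12.05 and 11.27 FPKM there and at 0.21 to 1.34 elsewhere, and Dbp at 9.88 and 9.83 against 69.33 to 181.56. Nr1d1, Cry1 and Hlf overlapped with the other libraries. Nr1d1 was at 51.91 and 41.69 FPKM in saline 1 and 3, at 93.28 in saline 2 and at 27.38 to 43.67 in the treated libraries. An effect of AngII stays open: the treated libraries scored -1.09 to -0.26 and saline 2, which had none, -0.88, but 1 library that lies with the AngII libraries for unknown reasons excludes nothing. Tissue taken at another time of day may also account for it: all 13 scored genes differed between saline 1 and 3 and saline 2 in the direction of a shifted phase. The arms were set after these genes were seen to differ and no collection time was given in the labels, so this count does not establish it, and differences between saline and the treated groups in clock-driven genes remain open.

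Ntn1 was lower with AngII and higher with PGE1, and an uneven share of the 2 sides of the first component in the groups may account for part of this. With a term for the sides the AngII+PGE1 vs AngII difference was 0.94 (SE 0.22, limma adjusted p = 0.12) against 1.66 without it. All AngII libraries lie on 1 side with only 1 AngII+PGE1 library, so the explanations cannot be told apart for this gene.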
